A study of Mus musculus with 8 samples.

How the data were processed

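The series holds 8 arrays of an Agilent mouse design hybridised with 2 colours, in 2 experiments of 4 arrays. Per the labels' protocols, total RNA was extracted with the Qiagen RNeasy kit, and 0.5 µg was amplified by a modified Eberwine-type procedure with the MessageAmp kit and labelled with Cy3 or Cy5. Samples were grouped by the source names of the Cy5 channel. Per the labels, the Cy3 source is SAMP8 vehicle on every array, although the strain field of that channel reads SAMR1 on the SAMR1 arrays. The source name was followed. The number of animals behind a sample, and whether both channels of a vehicle array held one RNA extract, are not given in the sources used here.

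The deposited files give, per probe, an intensity for the control and for the sample channel, the log2 ratio of sample over control, and a p-value. The authors' log2 ratio is the log2 of the deposited sample intensity over the control intensity, per the file headers and the values. Spot summary, background treatment, normalization and probe filter are not given in the sources used here. The lowest deposited intensity on any array was 29.6, so no full background subtraction is visible. Background left in the values would compress the ratios of dim probes, which was not measured. The labels state 3 spots per probe, while the files record 1 replicate. The authors' deposited table had a p-value under 0.05 for 51.2% of the probes on the PFC vehicle array and 35.3% on the HPC vehicle array, both self-hybridised, so these p-values measure agreement within an array and were not used as tests between groups. The deposited table of the whole series holds 28122 probes, and its log2 values equal those of the sample files, with a largest difference of 0.

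The probes carry 24585 Ensembl gene IDs. The table of names provided gives no Ensembl IDs, and 0 of the 24585 matched a symbol. The 36 gene lists fixed before the data were examined, written as symbols, could therefore not be evaluated, nor could the genes fixed by name. A gene's value was the mean over its probes. In 1204 PFC genes with several probes, the strain differences of a pair of probes correlated with an r of 0.27, and in 1296 HPC genes with 0.43, so probes of a gene often differed in size. For the strain difference, 18 PFC genes had a first probe over 1.5-fold, and the second probe had the same sign in 15 and also passed 1.5-fold in 4. In the HPC the second probe had the same sign in 12 of 14 and also passed in 7, and in the PFC at 0.32 mg/kg/day in 8 of 10 and in 1. In each region, the 25% of genes with the lowest mean log2 intensity were left out.

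Each comparison was the difference of 2 arrays' log2 ratios, array minus the vehicle array of its region, which removes the probe's dye effect. Genes were counted at 1.5-fold when the difference and the array's own ratio both passed in the same direction. These differences between single arrays were not tested, because each group has 1 array. Effects shared by both experiments were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 arrays, with region, SAMR1 and ORY-2001 as terms and 4 residual degrees of freedom, and again with a region by ORY-2001 interaction and 3 residual degrees of freedom. p-values were adjusted by Benjamini-Hochberg. These fits take doses together and place differences between experiments in the residual. Nothing in the labels says how samples relate to separate animals, so the p-values measure only the spread between these arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for the rest.

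Correlations between comparisons were computed across genes, with 100 simulated sets of arrays that share a vehicle array. Their noise came, within each of 10 intensity classes, from the variance of the vehicle array's log2 ratio less its covariance with the other arrays of its region. It stands for technical noise if both channels of a vehicle array held the same extract, and variation between samples is then not taken into account. The counting, the noise estimate and the estimate of a mixed sample were tested on simulated arrays, where a true noise SD of 0.1 was estimated as 0.1 and a true mixture of 25% as 26.3%. The counting found all 60 simulated strain genes in either region and all 200 genes changed 2-fold on the simulated HPC array at 3.2 mg/kg/day. The simulated strain changes were larger than 2-fold, so these counts do not show how well changes near 1.5-fold are found. On the simulated PFC array at 0.32 mg/kg/day the mixture shifted 60 genes, 30 of them by over 1.5-fold, and the counting found 28 of the 60. The limma fits were tested on simulated data with 200 changed genes.

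The rule for named genes was fixed before the data were examined. Per comparison it ranks genes by the smaller of the absolute difference and the absolute own ratio, and takes 10 per direction. For a limma effect it takes the 10 largest fold changes per direction among genes that pass, or the 5 smallest p-values per direction where fewer pass. Without names, only the first 2 per direction are printed. Alternatives fixed in advance were the own ratio without the vehicle array, a loess refit with a span of 0.3, no intensity filter, the lower 50% left out, the series table, a 2-fold threshold, the brightest probe per gene, and for limma also each array left out in turn and an intensity trend with a robust fit. Further alternatives and the tests of the closing section were chosen after seeing the data.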

Results

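Gene expression was measured in the brains of senescence-accelerated mice. SAMP8 is a strain prone to accelerated ageing with memory impairment, and SAMR1 is the related strain resistant to it that serves as its control. ORY-2001, also known as vafidemstat, is an inhibitor of the histone demethylase KDM1A and of monoamine oxidase B. The mice were 5 months old at the start and received ORY-2001 or vehicle in the drinking water. The labels give treatment times of 6, 8 or 16 weeks without saying which applied to which sample. In 1 experiment the prefrontal cortex (PFC) of males was studied at 0.32 and 0.96 mg/kg/day, and in the other the hippocampus (HPC) of females at 0.96 and 3.2 mg/kg/day. The source names of the PFC samples carry the words basal conditions, and those of the HPC samples do not. Brain region, sex, experiment and whatever this label stands for therefore cannot be told apart. Each experiment held 4 arrays, with 1 array for each of SAMR1 vehicle, SAMP8 vehicle and the 2 ORY-2001 doses, and there were no replicates. On every array the sample was labelled with Cy5 and SAMP8 vehicle RNA with Cy3. The SAMP8 vehicle array carried SAMP8 vehicle RNA in both channels.

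The PFC arrays held values for 17088 probes of 15552 genes, and the HPC arrays for 16180 probes of 14521 genes. The median Cy5 intensity lay between 77.4 and 81.9 on the PFC arrays and between 140.3 and 161.9 on the HPC arrays. The number of arrays, 1 per group, limits the precision. The files identify genes by Ensembl gene ID and do not pair the IDs with names, so genes are given by ID, with at most 2 higher and 2 lower per comparison.

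The self-hybridised arrays hold vehicle RNA in both channels and show the dye effect and the technical noise. Whether both channels held the same extract is not given, and the simulated values below are read as if they did. These arrays were therefore not taken as a measure of how far separate samples of a group differ, and no group has a second array. Among 11664 PFC genes above the intensity filter, 126 were over 1.5-fold higher and 24 over 1.5-fold lower in Cy5 than in Cy3 on the PFC vehicle array. Among 10890 HPC genes, 4 were higher and 1 was lower on the HPC vehicle array. Each comparison below therefore uses the difference between an array's log2 ratio and that of the vehicle array of its region. A gene is counted when this difference and the array's own log2 ratio both exceed 1.5-fold in the same direction. In simulated arrays that differ only by the noise of the vehicle array, an average of 3.1 PFC genes and 0.0 HPC genes were counted. This simulation leaves out variation between samples, so a count above it is not a measure of treatment or strain.

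**Figure D1:**
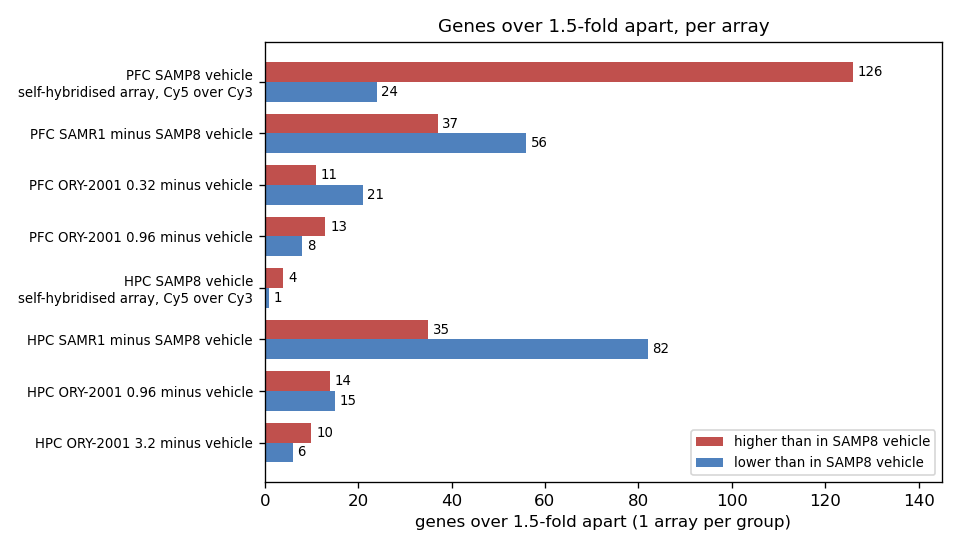
Number of genes over 1.5-fold apart (horizontal axis) for each array, with 1 array per group. Bars for the self-hybridised vehicle arrays count Cy5 over Cy3, 126 higher and 24 lower in the PFC against 4 and 1 in the HPC, and the other bars count differences from SAMP8 vehicle.

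The first question was how the brains of SAMR1 and SAMP8 mice differed. In the PFC, 37 genes were higher and 56 lower in SAMR1 than in SAMP8 vehicle. The gene ENSMUSG00000059442 was lower by a log2 difference of -4.01, and ENSMUSG00000070584 by -3.84. The gene ENSMUSG00000006740 was higher by 1.81 and ENSMUSG00000022490 by 1.69 on the log2 scale. These are differences between single arrays, with no replicate check and no p-value. The arrays' own ratios against Cy3 gave 172 higher and 89 lower genes, so the balance of the 2 directions depended on the subtraction of the vehicle array.

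In the HPC, 35 genes were higher and 82 lower in SAMR1 than in SAMP8 vehicle. The gene ENSMUSG00000074036 was lower by a log2 difference of -3.74 and ENSMUSG00000070584 by -3.66. The gene ENSMUSG00000006740 was higher by 2.69 and ENSMUSG00000025867 by 1.76. These values also come from 1 array per group.

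Over the 10177 genes above the filter in both experiments, 16 genes were higher in SAMR1 in both and 24 lower in both, where independent lists of these sizes would share 0.11 and 0.41. No gene over 1.5-fold apart in both experiments had opposite directions. These comparisons share no array. Across all 10177 genes, which are not independent replicates, Pearson's r of the strain differences was 0.22 and Spearman's rho -0.04.

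The strain effect shared by both experiments was tested in limma over all 8 arrays, with region as a block. Of 9879 genes, 75 passed a Benjamini-Hochberg adjusted p of 0.05. Relative to SAMP8, 36 of them rose and 39 fell in SAMR1, and all 75 had the same sign in both experiments. Selection on a coefficient shared by both experiments favours equal signs, so this is no separate evidence of agreement. Their fold changes ranged from 1.29 to 13.5, and 8 that rose and 13 that fell exceeded 2-fold. A strain difference in gene sequence or copy number should also be shared by both experiments, and was not told apart from one in expression. The gene ENSMUSG00000070584 fell by 3.75 ± 0.16 (SE) on the log2 scale, with a limma adjusted p of 8.37e-06. The gene ENSMUSG00000071005 fell by 3.59 ± 0.12 (SE), with a limma adjusted p of 2.14e-06. ENSMUSG00000006740 rose by 2.25 ± 0.33 (SE) with a limma adjusted p of 0.0191, and ENSMUSG00000022490 rose by 1.53 ± 0.18 (SE) with a limma adjusted p of 0.00644. The count ranged from 22 without the PFC vehicle array to 141 without the PFC SAMR1 array, and own ratios without either vehicle array gave 285. The calls of both genes that rose were lost without the PFC vehicle array, with limma adjusted p of 0.133 for ENSMUSG00000006740 and 0.0802 for ENSMUSG00000022490, and without the HPC SAMR1 array, with 0.0856 and 0.0527. That of ENSMUSG00000006740 was also lost without the HPC vehicle array, with 0.0581. The log2 differences then were 2.25 for ENSMUSG00000006740 without either one of the vehicle arrays and 1.67 without the HPC SAMR1 array, and 1.35 and 1.57 for ENSMUSG00000022490 without the PFC vehicle and the HPC SAMR1 array.

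**Figure D2:**
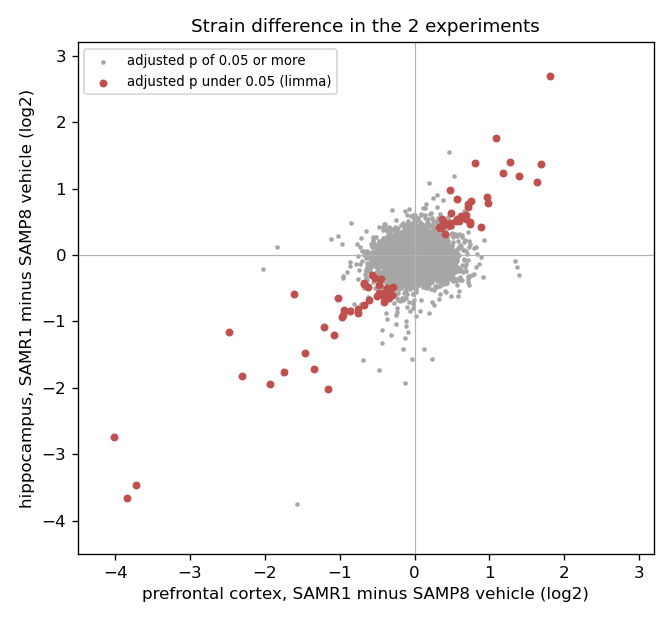
Log2 difference between SAMR1 and SAMP8 vehicle for each of 9879 genes, with the PFC on the horizontal axis and the HPC on the vertical axis. Red points are the 75 genes with a limma adjusted p under 0.05, all of which lie in the quadrants of equal sign, which selection on a shared coefficient favours.

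The second question was how ORY-2001 treatment of SAMP8 mice changed expression. In the PFC at 0.32 mg/kg/day, 11 genes were higher and 21 lower than in vehicle. The gene ENSMUSG00000021803 was lower by a log2 difference of -2.06 and ENSMUSG00000024871 by -1.59. The gene ENSMUSG00000064351 was higher by 1.90 and ENSMUSG00000075305 by 0.82. All 4 differed in the same direction on the untreated SAMR1 array, where ENSMUSG00000021803 was at -2.02, ENSMUSG00000024871 at -1.84, ENSMUSG00000064351 at 1.39 and ENSMUSG00000075305 at 1.35, so at these genes the single vehicle array stood apart from untreated SAMR1 as well. At genes that separated the strains in both experiments, this array lay at a median of 23.1% of the step from SAMP8 vehicle to SAMR1, and the PFC array of the higher dose at -2.1%. Of the 11 higher and 21 lower genes, 7 and 12 also passed 1.5-fold in the same direction in untreated SAMR1. At 2-fold, 1 gene was higher and 4 were lower than in vehicle. The array's own ratio against Cy3 gave 85 higher and 47 lower genes, which turned the balance of the 2 directions.

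**Figure D3:**
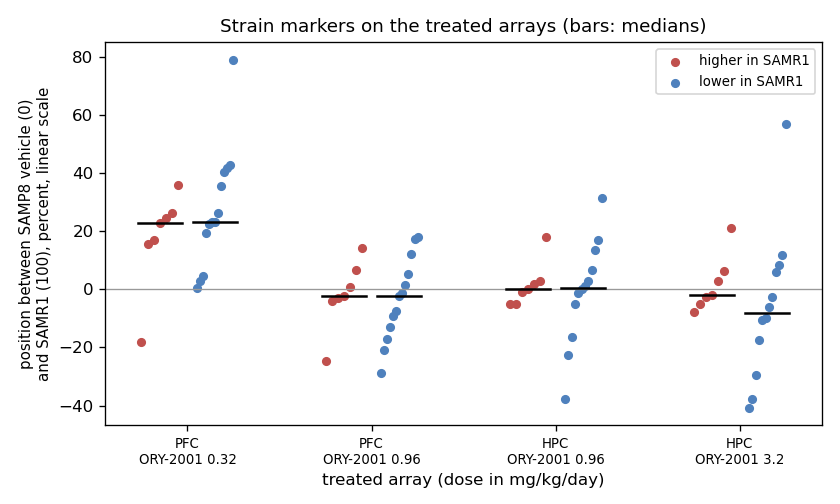
Position of each strain marker on the 4 treated arrays, in percent of the step from SAMP8 vehicle (0) to SAMR1 (100) on the linear scale. Each point is a gene over 2-fold apart between the strains in both experiments, black bars are medians, and the PFC array at 0.32 mg/kg/day has medians of 22.8% and 23.1% for markers higher and lower in SAMR1.

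In the PFC at 0.96 mg/kg/day, 13 genes were higher and 8 lower than in vehicle. ENSMUSG00000021803 was lower by -1.93 and ENSMUSG00000024871 by -1.55 on the log2 scale, against -2.02 and -1.84 on the untreated SAMR1 array. ENSMUSG00000073940 was higher by 1.96 and ENSMUSG00000052305 by 1.5. The arrays of the 2 doses shared 4 of their higher and 8 of their lower genes, all measured against the same vehicle array. Of these, 2 of the 4 higher and all 8 lower genes also passed 1.5-fold in the same direction in untreated SAMR1. Independent lists would share 0.01 of each, which leaves out the shared array. Simulated arrays that share its technical noise had 0.0 of each, which leaves out how far the vehicle sample itself differs from others, so neither value is what no effect would give. When the doses were set against each other without the vehicle array, 14 genes were higher and 3 lower at 0.96 than at 0.32 mg/kg/day. The own ratio at 0.96 mg/kg/day gave 63 higher and 25 lower genes.

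In the HPC at 0.96 mg/kg/day, 14 genes were higher and 15 lower than in vehicle. ENSMUSG00000052305 was lower by -1.73 and ENSMUSG00000076498 by -1.55 on the log2 scale, and the latter was at -1.57 on the untreated SAMR1 array. ENSMUSG00000047507 was higher by 1.08 and ENSMUSG00000037868 by 0.97. When the 50% of genes with the lowest intensity were left out, 8 were higher and 9 lower.

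In the HPC at 3.2 mg/kg/day, 10 genes were higher and 6 lower than in vehicle. ENSMUSG00000076498 was lower by -1.54 and ENSMUSG00000076490 by -1.15 on the log2 scale, against -1.57 and -1.41 on the untreated SAMR1 array. ENSMUSG00000047507 was higher by 1.5 and ENSMUSG00000040680 by 0.81, against 0.12 and -0.19 in untreated SAMR1. The arrays of the 2 doses shared 5 higher and 5 lower genes, all measured against the same vehicle array. All 5 lower genes and 0 of the 5 higher genes also passed 1.5-fold in the same direction in untreated SAMR1. Independent lists would share 0.01 of each and the simulated arrays 0.0, with the same limits as in the PFC. Set against each other without the vehicle array, 27 genes were higher and 8 lower at 3.2 than at 0.96 mg/kg/day. With the 50% of genes of lowest intensity left out, 5 genes were higher and 2 lower than in vehicle, and the own ratio gave 23 and 11.

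The differences at the 2 doses correlated across genes with Pearson's r of 0.76 in the PFC and 0.66 in the HPC (Spearman's rho 0.75 and 0.64). Both differences use the same vehicle array, and simulated arrays that share only its technical noise gave an r of 0.50 in either region. The simulated arrays of a region were given equal noise, which fixes this r at 0.50 whatever the size of the noise. The covariance was 0.0203 against 0.0179 simulated in the PFC, and 0.0114 against 0.0052 simulated in the HPC. The simulated values leave out the deviation of the vehicle sample itself, which both differences share, so an excess over them does not show agreement between doses. With 1 vehicle array per region the control could not be split. The arrays' own ratios, which leave the vehicle array out but share vehicle RNA in Cy3 and the dye effect, gave an r of 0.78 in the PFC and 0.64 in the HPC. Across regions, where no array is shared, Pearson's r between treatment differences lay between 0.02 and 0.15, and at 0.96 mg/kg/day no gene passed 1.5-fold in the same direction in both regions.

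Whether treated SAMP8 differed from vehicle in the same direction as SAMR1 was examined within each region. In the PFC, r with the strain difference was 0.72 at 0.32 and 0.56 at 0.96 mg/kg/day. The covariance was 0.0284 and 0.0171, against 0.0179 simulated from technical noise. The value above the simulated one was that of the 0.32 mg/kg/day array, which lay at a median of 23.1% of the strain step at the strain markers, against -2.1% for the other. In the HPC, r was 0.20 at 0.96 and 0.22 at 3.2 mg/kg/day, with a covariance of 0.0051 and 0.0058 against 0.0052 simulated. Of the strain genes of the PFC, 2 higher and 8 lower genes passed 1.5-fold in the same direction at both doses, and of those of the HPC 0 higher and 5 lower. The shared vehicle array enters all of these values, and the simulated ones leave out the deviation of the vehicle sample.

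No gene passed an adjusted p of 0.05 for an ORY-2001 effect shared by both experiments in limma, over 9879 genes. At an unadjusted p under 0.05 there were 929 genes. The smallest limma adjusted p was 0.0901, for ENSMUSG00000032417 with a log2 difference of 0.66 ± 0.08 (SE) and for ENSMUSG00000028871 with 0.70 ± 0.09 (SE). On the other side, ENSMUSG00000037359 had -0.49 ± 0.06 (SE) with a limma adjusted p of 0.102. In simulated data the fit called 85% of 200 genes changed 1.5-fold and 97.5% of those changed 2-fold. The simulated change was the same on every treated array, so these shares do not apply to changes that differ by dose or region. It also had its full size at every intensity, so the shares may be too high for dim genes if background compressed their ratios. The count was 12 without the HPC vehicle array and 2 without the PFC vehicle array. Own ratios without both vehicle arrays, which keep the dye effect, gave 29 higher and 11 lower genes.

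The difference of the ORY-2001 effect between the 2 experiments was tested as an interaction in limma. No gene of 9879 passed, and 442 had an unadjusted p under 0.05. The gene ENSMUSG00000036446 had the smallest adjusted p, 0.417 in limma, with the effect in the HPC larger by 0.78 ± 0.09 (SE) on the log2 scale. In simulated data this fit called 32% of 200 genes that differed 1.5-fold and 83% of those that differed 2-fold. The simulated difference was the same on each treated HPC array and had its full size at every intensity, with the same limit for dim genes. Leaving out either vehicle array gives the same fit, in which SAMR1 and not vehicle is the control for ORY-2001. Leaving out either SAMR1 array likewise gives the same fit, with vehicle as the control. The count was 16 when the vehicle array of one experiment or the other was left out, and 5 when a SAMR1 array was left out.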

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

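At 0.96 mg/kg/day, the dose studied in both experiments, 5 genes passed 1.5-fold in opposite directions, all higher than vehicle in the PFC and lower than vehicle in the HPC. Their log2 differences ranged from 0.60 to 1.96 in the PFC and from -1.73 to -0.78 in the HPC. In a test chosen after these values had been seen, limma compared the departure of the 0.96 mg/kg/day array from the other 3 arrays of its region between the regions, with 4 residual degrees of freedom. Of 9879 genes, 2 passed an adjusted p of 0.05, both among the 5, and 84 had an unadjusted p under 0.05. ENSMUSG00000052305 differed between the regions by 3.06 ± 0.27 (SE) on the log2 scale with a limma adjusted p of 0.0228, and ENSMUSG00000073940 by 3.30 ± 0.34 (SE) with 0.0372. The other 3 had limma adjusted p between 0.0625 and 0.0773. The fit takes a single array to vary like the others, and among the 16 pairs of a PFC and an HPC array 7, the real one included, gave as many genes, with 29 as the highest of the others. Region, sex, experiment and the label of basal conditions coincide, so none of them can be named as the source of the difference. The difference also rests on the single 0.96 mg/kg/day array of each region. A deviation of either single sample therefore cannot be told apart from an effect of treatment. ENSMUSG00000052305 was higher by 1.5 in the PFC and lower by -1.73 in the HPC, at the 97.5th percentile of intensity on the HPC arrays. The other dose of each region did not share the difference: these 5 genes lay between -0.55 and -0.03 in the PFC at 0.32 mg/kg/day and between -0.31 and 0.11 in the HPC at 3.2 mg/kg/day, and 0 of them passed 1.5-fold there. No gene passed in the same direction in both regions.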

How the results depend on the processing

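Beyond region as a block in the limma fits, no paired analysis was possible because each group has 1 array. The gene list alternatives were not run, since no gene had a name. The counts per comparison stayed within 1.5 times under a loess refit, no filter and the brightest probe. The series table holds the same values as the sample files and gave the same counts, so it is no separate check. With each array's own ratio against Cy3, the PFC counts became 261 for SAMR1, 132 (85 higher, 47 lower) at 0.32 and 88 (63 higher, 25 lower) at 0.96 mg/kg/day, and the HPC count at 3.2 mg/kg/day became 34 (23 higher, 11 lower). This ratio keeps the dye effect. At 2-fold the counts were 27, 5 and 5 in the PFC and 40, 8 and 5 in the HPC. With the 50% of genes of lowest intensity left out, the HPC counts were 17 at 0.96 and 7 at 3.2 mg/kg/day, with fewer genes tested. In limma, own ratios without the vehicle arrays called 285 genes for strain and 40 (29 higher, 11 lower) for ORY-2001, and 0 for the interaction. Leaving out 1 array at a time gave 22 to 141 genes for strain, 0 to 12 for ORY-2001 and 0 to 16 for the interaction. Without the PFC 0.32 mg/kg/day array, strain gave 55. Untreated arrays of both strains as control, chosen after seeing the data, gave 6 genes for ORY-2001. The correlation of the strain differences between regions became 0.44 with own ratios. Without the genes over 1.5-fold apart between the strains in the HPC, also chosen after seeing the data, the PFC counts were 27 at 0.32 and 20 at 0.96 mg/kg/day. This setting keeps genes that were apart between the strains only in the PFC. There, 7 of the higher and 12 of the lower genes at 0.32 mg/kg/day also passed in the same direction in SAMR1. Except where a reason is given, the cause was not tested. Low signal over background limits dim genes, whose ratios may be compressed.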

Other observations

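All tests in this part were chosen after the values they bear on had been seen.

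Treated arrays were also set against the untreated arrays of both strains, 4 against 4, in limma with region as a block. This fit was tried after the shared ORY-2001 fit had called 0 genes, and it was prompted by the values of ENSMUSG00000032417, a gene it then calls, so it is not independent evidence for that gene. It called 6 of 9879 genes, all higher on treated arrays by 1.37 to 1.59-fold, with limma adjusted p between 0.0328 and 0.0367. In each region both treated arrays lay above both untreated ones for all 6. Selection on this difference favours such a separation, so it is no separate evidence. ENSMUSG00000028871 was higher by 0.67 ± 0.07 (SE) and ENSMUSG00000032417 by 0.60 ± 0.07 (SE) on the log2 scale, and against the vehicle arrays alone the 6 genes had limma adjusted p between 0.0901 and 0.128. Of the 34 splits of the 8 arrays that could be fitted, 1, the real one, gave as many genes. The highest of the others gave 5, in the split that parts each 0.96 mg/kg/day array from the rest of its region. With region as a block, the comparable splits are the 18 with 2 arrays of each region on each side, where the real one called 6 genes and the others 0, and 18 are too few for a share under 0.05.

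The PFC array at 0.32 mg/kg/day lay part of the way to SAMR1 at 20 genes over 2-fold apart between the strains in both experiments. On the linear scale, 19 of the 20 were displaced toward SAMR1, by a median of 23.1% of the strain step. Medians were 22.8% at markers higher in SAMR1 and 23.1% at markers lower in SAMR1, as SAMR1 RNA mixed into the sample would give. But single markers ranged from -18.0% to 79.1%, an SD of 19.9% against 13.4% on the PFC array at 0.96 mg/kg/day. The interquartile width, which single markers affect less, was 19.2% against 15.8%. The 100 other genes nearest in intensity to each marker lay at a median of -0.7% of the strain step, with quartiles of -2.4% and 0.8% against 16.6% and 35.8% for the markers, against a dye trend with intensity as the cause, and the array at 0.96 mg/kg/day stood at -2.1%, against a treatment effect that holds at the higher dose. A mixed sample may account for the pattern, while an effect of the lower dose alone and genetic variation among the SAMP8 mice stay open and untested.

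Some strain differences were shared by both treated arrays of a region, 10 in the PFC and 5 in the HPC, all measured against 1 vehicle array per region. Of the 14 measured in the other region, 0% had the same strain difference there, against 42.8% of the 173 that passed on neither treated array. This is what expression particular to the vehicle sample of each region would give. The strain differences of the other region hold no treated array, so a limit of the ORY-2001 effect to a region or sex would not change them. An effect of ORY-2001 toward SAMR1 would give the pattern only if the strain difference at these genes was itself limited to a region or sex. The explanations cannot be told apart, because region, sex and experiment coincide and each region has 1 vehicle array.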
